A study of Mus musculus with 13 samples.

How the data were processed

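Livers of C57 BL6 mice aged 8 weeks were collected 6 h after injection. The labels give intraperitoneal D-galactosamine at 500 mg/kg with lipopolysaccharide at 5 µg/kg, and dmPGE2 at 300 µg/kg, given 1 h earlier in the pretreated group. For dmPGE2 alone no such interval was recorded, so the time from dmPGE2 to collection may differ between these groups. There were 3 saline, 3 GalN/LPS, 4 pretreated and 3 dmPGE2 libraries, made per the labels with the NEBNext Ultra RNA kit from 1 µg of total RNA each. The labels do not say whether each library came from its own animal. If some did not, the p-values measure only the spread between these samples. Columns of the tables were matched to samples by group name and replicate number. The series description speaks of AILI mice, while the sample labels give D-galactosamine with lipopolysaccharide, and the labels were followed. The 3 columns named ALF were taken as the GalN/LPS group, since every other column name carried saline controls or dmPGE2.

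The deposited values were of 2 kinds. The authors gave raw read counts per Ensembl gene, which were checked to be whole numbers, and FPKM for the same libraries. In the deposited FPKM the count is divided by gene length and by a denominator per library. That denominator, recomputed from both tables, lay between 0.706 and 1.28 times the library total, and how it was set is not given in the sources used here. It lay close to the TMM factor of the library, with 0.706 and 0.683 in pretreated 4, 0.934 and 0.904 in GalN/LPS 2, and 1.28 for both in dmPGE2 1. The alternatives on FPKM are thus no independent check on the scaling. The submitters' processing notes name HISAT2, with no version, and GRCm38/mm10. The read counter, the annotation release and the use of strand are not given in the sources used here. Coordinates are those of the deposited tables.

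The table held 54532 genes. Total counts ranged from 17018104 to 18425824 in saline, 16575171 to 17709049 in GalN/LPS, 16910816 to 17649675 in pretreated and 14829838 to 20777809 in dmPGE2 libraries. The filter of edgeR by group kept 14280 genes, which held 99.9% of all counts. TMM factors ranged from 1.17 to 1.18 in saline, 0.904 to 1.14 in GalN/LPS, 0.683 to 0.830 in pretreated and 1.16 to 1.28 in dmPGE2 libraries. They differ between groups, so results with library totals in their place are given beside those they change. Counting intervals (95%, exact Clopper-Pearson) and floors of 3 counts over a group cover counting error only.

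All 13 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with group as the only term, and tested with its quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0390 with 9 residual and 6.80 prior degrees of freedom. The comparisons were GalN/LPS against saline, pretreated against GalN/LPS, dmPGE2 against saline, pretreated against saline, and the interaction (the effect of dmPGE2 in injured less that in uninjured livers). The interaction takes no account of a possible difference in the time after dmPGE2. Standard errors were taken from the log2 fold change and the F statistic. Principal components used log2 CPM (prior count 2) of the 2000 most variable genes. To see what sharing the GalN/LPS group does to 2 comparisons, 20 sets of saline, GalN/LPS and pretreated libraries were simulated with the GalN/LPS levels in all of them.

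Gene sets were 39 lists of 633 entries (618 distinct genes, 2 of them without a match in the table), of which 38 had at least 5 measured members and were tested. The list of pancreas and gut markers had too few and is not reported. Camera of limma 3.58.1, which compares the genes of a list with all others, was run with a preset correlation of 0.01 and again with an estimated one. Fry, which asks whether a list moves on balance one way, was run beside it, with its test for change in either direction. Counts adjusted over the list alone use only the p-values of the list's members. For camera the signs of a list's median and of the test differed in 5, 3, 4, 4 and 1 of the 38 lists in the order GalN/LPS against saline, pretreated against GalN/LPS, dmPGE2 against saline, pretreated against saline and interaction.

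Genes to be named were set by a rule. In each comparison it took the 8 genes with the largest changes each way among those past the test with no overlap between groups, a mean of at least 5 CPM in the higher group and an established symbol. For the interaction the overlap was not required. It added up to 4 members of each list with the smallest adjusted p, and always the prostaglandin E receptors, Ptgs2, Hpgd, Tnf, Il1b, Il6 and Alb. From these, the genes named in the text were picked after their values were seen, and some that the rule gives are not reported here. Of the 129 named genes, 19 overlapped another tested gene by position, and in 3 of them (Fdft1, Ptger4 and mt-Co3) the other gene had more counts. The comparisons with their tests, the lists, the naming rule and the alternatives were set before the data were examined, except the alternative that leaves out 2 libraries together. The explanations weighed for patterns were chosen once the patterns had been seen, most of them before the values that test them.

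Alternatives were DESeq2 1.42.0, voom with sample quality weights, RLE size factors, library totals, no filter on low counts, a filter of CPM of at least 1 in at least 3 libraries, the replicate number as a block, a log2 fold change of at least 1, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, the former also with no filter, a fit of only the groups compared, and leaving out each library in turn. Genes with no adjusted p in DESeq2 counted as not called. The edgeR fit with no filter was not tried on simulated data, so its calls are uncertain in every comparison. In the group of 4 each sample was tested with Dixon's ratio. Groups of 3 were not tested that way. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

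The pipeline was tested on simulated data with changes planted in 200 of 14280 genes. For pretreated against GalN/LPS libraries edgeR found 13.4%, 71.6% and 93.9% of genes changed by 1.5, 2 and 4 fold, and called 8 of 14080 unchanged genes. For dmPGE2 against saline it found 9%, 65.7% and 100%, and called 7 of 14080. A list of 20 genes shifted by 1.5 fold was found by camera with an estimated correlation in both designs, on 14159 genes for pretreated against GalN/LPS and 14036 for dmPGE2 against saline (adjusted p = 1.55e-05 and adjusted p = 9.39e-05), with 0 of 37 other lists called. Genes were simulated independently of each other, while the shifted list, cholesterol synthesis, had an estimated correlation of 0.523 in the real pretreated against GalN/LPS livers. The simulation thus does not show what camera finds, or wrongly calls, among correlated genes. Reads, splicing and sequence variants were not analysed here.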

Results

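Mouse livers were profiled by RNA sequencing after D-galactosamine with lipopolysaccharide (GalN/LPS), a model of acute liver failure. Galactosamine depletes uridine nucleotides in hepatocytes and so blocks their transcription, which makes them sensitive to the tumor necrosis factor that lipopolysaccharide evokes. The stable prostaglandin E2 analogue 16,16-dimethyl prostaglandin E2 (dmPGE2) was given before the injury or alone. The 13 libraries came from 4 groups: saline (n = 3), GalN/LPS (n = 3), dmPGE2 followed by GalN/LPS (pretreated, n = 4) and dmPGE2 alone (n = 3). Values after ± are standard errors for log2 fold changes and SD for mean levels, and levels are TMM-scaled CPM.

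The first principal component held 78.0% of the variance and separated the injured from the uninjured livers. Saline livers scored from -67.4 to -56.6, dmPGE2 livers from -66.2 to -60.7, pretreated livers from 34.8 to 43.2 and GalN/LPS livers from 67.2 to 81.4. On the second component, with 9.38% of the variance, the GalN/LPS livers scored from 19.8 to 31.6 and the pretreated livers from -35.3 to -16.2. Ribosomal RNA genes took 0.153 ± 0.0364% of the counts in saline, 1.23 ± 0.197% in GalN/LPS, 0.466 ± 0.0696% in pretreated and 0.121 ± 0.0532% in dmPGE2 livers. Hemoglobin mRNAs took 0.0401 ± 0.0287%, 0.138 ± 0.0618%, 0.0479 ± 0.0133% and 0.0428 ± 0.00283% in the same order. Albumin mRNA (Alb) alone took 7.53%, 7.94%, 9.15% and 5.85%, and mitochondrial genes 5.52 ± 1.79%, 7.21 ± 0.253%, 3.44 ± 0.791% and 3.55 ± 0.407%.

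**Figure D1:**
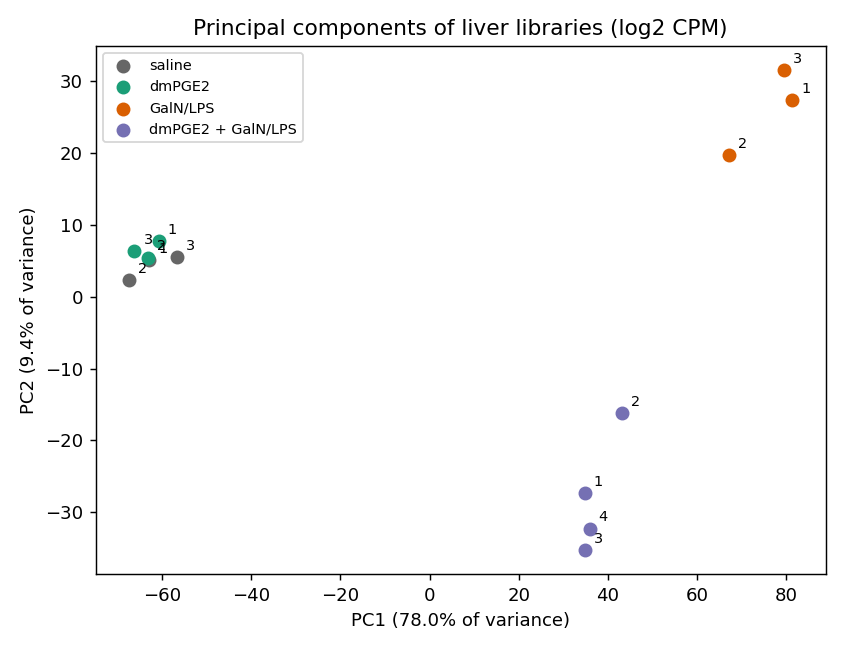
Scores of the 13 libraries on the first (78.0% of the variance) and second (9.38%) principal components of log2 CPM, 1 point per library, labelled by replicate number and coloured by group. Pretreated livers, from 34.8 to 43.2 on the first component, lay between the GalN/LPS livers (67.2 to 81.4) and the saline livers (-67.4 to -56.6).

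GalN/LPS raised inflammatory mRNAs, some of them almost absent from saline livers. The chemokine mRNA Cxcl10 rose from 1.86 ± 0.824 to 349.5 ± 61.8 CPM (log2 fold change 7.55 ± 0.27, adjusted p = 3.32e-11, n = 3 against 3). Il1b, the mRNA of interleukin 1 beta, rose from 0.915 ± 0.379 to 165 ± 34.3 CPM (7.47 ± 0.30, adjusted p = 6.85e-11). The itaconate-producing enzyme Acod1 of activated macrophages (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573) rose by 10.69 ± 0.43. In the opposite direction, mRNAs of hepatocyte transcription factors fell, such as the bile acid receptor Nr1h4 (-2.63 ± 0.14). Of 14280 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3906 were higher and 3650 lower. At least 2-fold changes made up 2674 and 1853 of these. More genes were lower than higher with library totals (3067 higher, 4277 lower), with no filter on low counts (3802, 4272), on filtered FPKM (2823, 3348) and without GalN/LPS 3 (3156, 3826).

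All 21 measured members of the inflammatory cytokine and chemokine list rose, also when adjusted over the list alone (21), with a median log2 fold change of 6.79. The median was 6.76 with 3 genes at the bound their counts allow. Ccl2 (chromosome 11, 82035571 to 82037453) rose by 9.34 ± 0.49, Cxcl2 by 10.19 ± 1.03 and Tnf by 6.76 ± 0.44. Cxcl2 had counts in saline 3 alone of the saline libraries (0.288 CPM), so the size of its change is uncertain. Csf3 and Il6 had no counts in saline livers and were at least 210-fold and at least 59.3-fold higher, against a floor of 3 counts over the group. Ch25h, which makes 25-hydroxycholesterol, had 1 count in saline and 2282 in GalN/LPS livers, a ratio of 2640 with a 95% counting interval from 473 to 104000. The cystine transporter Slc7a11, with no counts in saline, was at least 175-fold higher. In the list of NF-kB feedback and adhesion genes all 17 rose (17 adjusted over the list alone, median 3.52), including Tnfaip3 (6.12 ± 0.30), Icam1 (3.98 ± 0.21) and Nfkbia (2.70 ± 0.14). Interferon response genes rose in 20 of 23 cases (20 adjusted over the list alone, median 2.30), with Gbp2 at 7.17 ± 0.34 and Irf1 at 2.77 ± 0.15. Gbp2 belongs to a gene family with similar sequences, so its reads are uncertain in origin.

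Genes of inflammatory cell death rose with them. Of 13 necroptosis and pyroptosis genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Casp4 at 5.15 ± 0.21 and Nlrp3 at 5.60 ± 0.32. The 22 apoptosis genes were split, with 11 higher, 7 lower and 4 not past the test (11 and 7 adjusted over the list alone). Among them Pmaip1 rose by 5.12 ± 0.34 and Apaf1 by 3.62 ± 0.32, while Fadd fell (-1.74 ± 0.20). Immediate early genes rose in 18 of 20 cases (18 adjusted over the list alone), with Klf6 at 3.92 ± 0.25, Fosl2 at 3.42 ± 0.25 and Klf2 at 3.45 ± 0.19. Camera called that list at adjusted p = 1.47e-10, but adjusted p = 0.0962 with an estimated correlation.

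Markers of many cell types other than hepatocytes were higher in GalN/LPS livers. All 12 neutrophil markers rose (12 adjusted over the list alone, median 6.64), as did all 9 monocyte markers (9, median 5.39), with Mmp8 at 7.39 ± 0.31, Il1r2 at 8.89 ± 0.39 and Cd14 at 6.30 ± 0.26. Of 12 Kupffer cell and macrophage markers 11 rose (11 adjusted over the list alone), including Cd68 (3.05 ± 0.24) and Adgre1 (3.40 ± 0.28). All 12 sinusoidal endothelial markers rose (12 adjusted over the list alone), among them Dnase1l3 (3.61 ± 0.21), Stab1 (2.48 ± 0.20) and Clec4g (2.33 ± 0.17). Stellate cell and fibroblast markers rose in 9 of 11 cases (10 adjusted over the list alone), with Dcn at 2.86 ± 0.36. Camera's calls for the last 3 lists were lost with an estimated correlation, at adjusted p = 0.236 for Kupffer cells, adjusted p = 0.105 for endothelium and adjusted p = 0.42 for stellate cells with an estimated correlation. T and NK cell markers rose in 9 of 12 cases (9 adjusted over the list alone), with granzyme Gzmb at 5.22 ± 0.43, and B cell markers in 4 of 7 (6 adjusted over the list alone, camera adjusted p = 0.0723). Erythroid and platelet markers rose in 8 of 9 cases (8 adjusted over the list alone, median 1.80; adjusted p = 0.351 with an estimated correlation). Of 8 cholangiocyte markers 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 1.92; adjusted p = 0.236 with an estimated correlation).

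Hepatocyte programs did not fall together. Of 18 hepatocyte transcription factors 13 fell, 1 rose and 4 were not past the test (13 and 1 adjusted over the list alone, median -1.81), with Prox1 at -2.77 ± 0.22 and Rxra at -2.20 ± 0.19. Of the 18 secreted plasma proteins 0 passed the test in either direction (0 adjusted over the list alone, median 0.23). Alb was 64078 ± 6639 CPM in saline and 76989.7 ± 14585 CPM in GalN/LPS livers (0.26 ± 0.26, adjusted p = 0.42). Plg (0.40 ± 0.20, adjusted p = 0.103) and Apob (0.42 ± 0.20, adjusted p = 0.0893) did not pass, but Plg passed without saline 3 (0.56, adjusted p = 0.0451) and Apob without GalN/LPS 1 (0.58, adjusted p = 0.0296) and with DESeq2 (0.40, adjusted p = 0.0415). Without GalN/LPS 2 the changes of Alb, Plg and Apob were 0.10, 0.17 and 0.14, and without saline 2 that of Plg was 0.22. The 21 acute-phase genes were mixed, with 4 higher, 5 lower and 12 not past the test (4 and 3 adjusted over the list alone), with Saa3 at 3.84 ± 0.56 and the iron hormone Hamp at -1.92 ± 0.56. Saa3 and Hamp have close relatives in the genome, so their reads are uncertain in origin.

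Many cholesterol synthesis mRNAs fell. Of 20 cholesterol synthesis genes 14 fell and 0 rose (15 lower adjusted over the list alone, median -1.21), with Hmgcs1 at -2.54 ± 0.25. Camera gave that list adjusted p = 0.000584, and adjusted p = 0.44 with an estimated correlation. Of 15 fatty acid synthesis genes 7 fell and 1 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.225), led by Srebf1 at -2.22 ± 0.35. Of 18 bile acid genes 6 rose, 3 fell and 9 were not past the test (6 and 3 adjusted over the list alone). The list's median was 0.30, its mean -0.03 and camera's direction down (adjusted p = 0.784). The fallen members included the bile acid enzymes Cyp7a1 (-3.83 ± 0.38) and Cyp8b1 (-2.74 ± 0.33). In the list of gluconeogenesis and glycogen 7 of 14 genes fell and 2 rose (7 and 2 adjusted over the list alone), with G6pc at -2.85 ± 0.17 and Foxo1 at -1.99 ± 0.17 (camera adjusted p = 0.0284, and adjusted p = 0.351 with an estimated correlation). Of 16 urea cycle and amino acid genes 6 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0837). The urea cycle activator Nags, at -4.64 ± 0.22, fell too, beside Extl1 (-5.45 ± 0.53), the activin subunit Inhbe (chromosome 10, 127348857 to 127354411, -5.03 ± 0.34), Hdhd3 (-4.85 ± 0.28), Usp2 (-4.54 ± 0.22) and Anks4b (-4.17 ± 0.22). All 27 cytosolic ribosomal protein mRNAs rose slightly (27 adjusted over the list alone, median 0.55, Rps3 0.84 ± 0.13). With library totals in place of TMM 16 of them rose (median 0.37), and camera's adjusted p = 0.00292 became adjusted p = 0.551 with an estimated correlation. Their many processed pseudogenes leave some reads uncertain.

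Camera with its preset correlation called 22 of 38 tested lists in this comparison, and with an estimated correlation 10 calls held. These were the lists of cytokines, NF-kB feedback, interferon response, necroptosis and pyroptosis, hepatocyte transcription factors, prostaglandin pathway, coagulation, neutrophils, monocytes, and T and NK cells. Of all 14280 genes 8532 had no overlap between the libraries of the groups, where chance gives 10% for 3 against 3.

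Livers given dmPGE2 1 h before GalN/LPS had less of many inflammatory mRNAs. Nfkbia fell from 154 ± 12.1 to 31.7 ± 2.63 CPM (log2 fold change -2.28 ± 0.13, adjusted p = 1.04e-07, n = 4 against 3). Il1b fell from 165 ± 34.3 to 28.5 ± 6.51 CPM (-2.53 ± 0.20, adjusted p = 1.08e-06) and Cxcl10 from 349.5 ± 61.8 to 56.5 ± 3.60 CPM (-2.63 ± 0.19, adjusted p = 6.54e-07). The mRNAs of the cholesterol synthesis enzyme Msmo1 (58.6 ± 11.6 to 197 ± 28.1 CPM) and of plasminogen, Plg (1832 ± 461 to 3918 ± 214 CPM), rose. In all, 3481 genes were higher and 4299 lower in pretreated than in GalN/LPS livers, and 518 and 2603 of these by at least 2-fold. Scaling by library totals gave 616 higher and 6804 lower, so the higher share of calls was 44.7% with TMM and 8.3% with totals. The median of all genes moved from -0.10 to -0.61 with it.

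All 21 cytokine and chemokine genes fell (21 adjusted over the list alone, median -2.60), with Ccl2 at -3.86 ± 0.30, Il6 at -2.94 ± 0.51 and Tnf at -1.85 ± 0.28. Camera gave adjusted p = 5.37e-19 and adjusted p = 0.064 with an estimated correlation. All 17 NF-kB feedback and adhesion genes fell (17 adjusted over the list alone, median -2.18), including Birc3 (-2.22 ± 0.14) and Icam1 (-2.39 ± 0.18). This was the single list of the comparison whose camera call held, at adjusted p = 0.0474 with an estimated correlation, out of 25 called with the preset one. Of 23 interferon response genes 22 fell (23 adjusted over the list alone), with Irf1 at -2.26 ± 0.14 and the family member Gbp5 at -2.21 ± 0.19 (adjusted p = 0.164 with an estimated correlation). All 20 immediate early genes fell (20 adjusted over the list alone), with Fosl2 at -2.55 ± 0.22 and Klf6 at -2.15 ± 0.21 (adjusted p = 0.223 with an estimated correlation). Large falls were also those of the protein kinase A anchor Akap12 (chromosome 10, 4266380 to 4359470, -4.01 ± 0.52), the ubiquitin-like Ubd (-3.99 ± 0.33), Ch25h (-3.93 ± 0.44) and Ptgs2, the inducible cyclooxygenase (-3.91 ± 0.55).

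**Figure D2:**
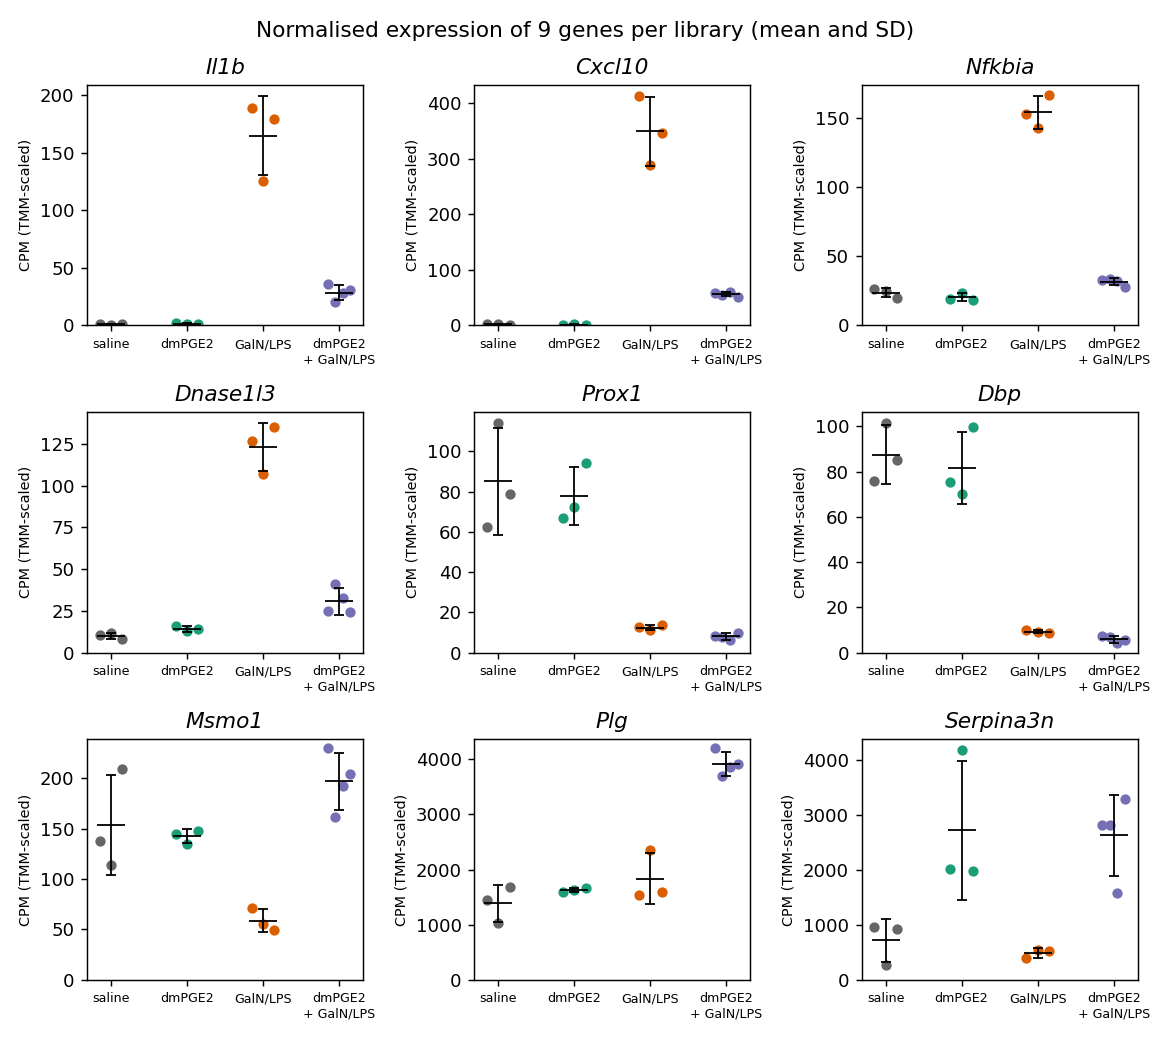
TMM-scaled CPM of 9 genes in the 13 libraries, 1 point per library by group, with the mean and SD of each group. Nfkbia lay at 154 ± 12.1 CPM in GalN/LPS and at 31.7 ± 2.63 CPM in pretreated livers, while Prox1 was below its saline level (85.0 ± 26.4 CPM) in both, at 12.4 ± 1.16 and 8.03 ± 1.55 CPM.

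Many apoptosis, necroptosis and pyroptosis genes were lower in pretreated livers. Of 22 apoptosis genes 15 fell, 2 rose and 5 were not past the test (16 and 2 adjusted over the list alone). The protective Mcl1 (-1.46 ± 0.14) and Cflar (-1.19 ± 0.14) were among those that fell, and the camera call gave adjusted p = 0.243 with an estimated correlation. Of 13 necroptosis and pyroptosis genes 9 fell and 0 rose (9 adjusted over the list alone), with Nlrp3 at -2.51 ± 0.23 and Casp4 at -1.77 ± 0.15 (adjusted p = 0.235 with an estimated correlation). The 13 ferroptosis genes went both ways, with 5 higher, 5 lower and 3 not past the test (6 and 5 adjusted over the list alone, 0 and 6 with library totals, median 0.15, camera adjusted p = 0.819).

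Many cell type markers fell as well, with medians nearer 0 than that of the cytokines. Of 12 neutrophil markers 10 fell (10 adjusted over the list alone, median -1.36), with Trem1 at -2.22 ± 0.21, Il1r2 at -1.66 ± 0.20 and Mmp8 at -1.05 ± 0.18. Of 9 monocyte markers 7 fell (7 adjusted over the list alone), with Cd14 at -1.64 ± 0.18. All 12 Kupffer cell markers fell (12 adjusted over the list alone, median -1.02), including Adgre1 (-1.71 ± 0.24) and Csf1r (-1.04 ± 0.18). All 12 sinusoidal endothelial markers fell (12 adjusted over the list alone, median -1.42), including Clec4g (-1.71 ± 0.15), Dnase1l3 (-2.00 ± 0.18) and Stab1 (-1.08 ± 0.17). Stellate cell and fibroblast markers fell in 9 of 11 cases (9 adjusted over the list alone), with Dcn at -1.57 ± 0.31 and Col1a2 at -1.82 ± 0.30. All 7 B cell markers fell (7 adjusted over the list alone), with Cd74 at -1.56 ± 0.24. With an estimated correlation these 6 lists had adjusted p = 0.247 (neutrophil), adjusted p = 0.277 (monocyte), adjusted p = 0.344 (Kupffer), adjusted p = 0.243 (endothelial), adjusted p = 0.348 (stellate) and adjusted p = 0.235 (B cell). Cholangiocyte markers fell in 5 of 8 cases (7 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation). Camera did not call T and NK cell markers, of which 7 of 12 fell (7 adjusted over the list alone, adjusted p = 0.112), or erythroid and platelet markers, of which 5 of 9 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.323).

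With TMM, many hepatocyte metabolic and secretory mRNAs were higher in pretreated livers. Of 20 cholesterol synthesis genes 17 rose and 0 fell (18 adjusted over the list alone, median 1.35), with Msmo1 at 1.75 ± 0.20, Cyp51 at 1.35 ± 0.18 and Fdft1 at 1.43 ± 0.18. Fdft1 overlaps the more abundant Ctsb on the other strand, so its reads are uncertain. With library totals 13 of the list rose (median 0.82), and the camera call gave adjusted p = 0.243 with an estimated correlation. Of 18 plasma proteins 16 rose (16 adjusted over the list alone, median 0.75), with Plg at 1.10 ± 0.19, Apob at 0.92 ± 0.19 and Serpinc1 at 0.85 ± 0.16. With library totals 5 rose (median 0.26), and adjusted p = 0.28 with an estimated correlation. Alb, at 126379 ± 38809.6 CPM, rose by 0.72 ± 0.25 (adjusted p = 0.0246), a call near the threshold. It was lost, at about the same size, without GalN/LPS 1 (0.60, adjusted p = 0.0966), GalN/LPS 3 (0.67, 0.0704), pretreated 3 (0.58, 0.0931) or pretreated 4 (0.59, 0.0838). With library totals the change was smaller (0.20, adjusted p = 0.327). The call was also lost with the replicate number as a block (0.56, adjusted p = 0.146), in a fit of only the groups compared (0.70, 0.0677) and on unfiltered FPKM (0.62, 0.263).

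Acute-phase genes rose in 17 of 21 cases (17 adjusted over the list alone, 15 with library totals), with Saa4 at 1.87 ± 0.28 and Serpina3n at 2.42 ± 0.41. Both belong to families with similar sequences. Of 18 bile acid genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, 8 and 1 with library totals), with Baat at 1.13 ± 0.14, the uptake transporter Slc10a1 at 1.12 ± 0.16 and Cyp7a1 at 1.99 ± 0.34. Of 16 urea cycle and amino acid genes 15 rose (15 adjusted over the list alone, 6 higher and 1 lower with library totals), with Cps1 at 1.34 ± 0.27, Tat at 1.79 ± 0.32 and Prodh at 1.26 ± 0.20. Fatty acid synthesis genes rose in 11 of 15 cases (11 adjusted over the list alone, 4 higher and 1 lower with library totals), with Acacb at 1.51 ± 0.27. Of 16 cytochrome P450 genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, 4 and 1 with library totals), with Cyp1a2 at 1.21 ± 0.24. Gluconeogenesis genes rose in 10 and fell in 4 of 14 cases (10 and 4 adjusted over the list alone), with Pck1 at 1.22 ± 0.17, but with library totals 3 rose and 4 fell. With an estimated correlation these 6 lists had adjusted p = 0.344 (acute-phase), adjusted p = 0.243 (bile acid), adjusted p = 0.277 (urea cycle), adjusted p = 0.277 (fatty acid synthesis), adjusted p = 0.277 (P450) and adjusted p = 0.316 (gluconeogenesis). Ribosomal protein mRNAs rose in 17 of 27 cases (18 adjusted over the list alone, median 0.35, Rpl3 0.62 ± 0.13), a direction that flipped with library totals (0 higher, 2 lower, median -0.16). Camera's adjusted p = 0.000572 for them became adjusted p = 0.431 with an estimated correlation.

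Few hepatocyte transcription factors rose beside the plasma proteins. Of 18 genes 3 were higher, 8 lower and 7 not past the test in pretreated against GalN/LPS livers (4 and 8 adjusted over the list alone, 0 and 12 with library totals, camera adjusted p = 0.304). Cebpb (-1.60 ± 0.19), Nr5a2 (-0.97 ± 0.17) and Foxa1 (-1.45 ± 0.28) were among those that fell, whereas Nr1h4 rose by 0.67 ± 0.13, though not with library totals (0.15, adjusted p = 0.367). Large rises were those of the histone methyltransferase Setdb2 (chromosome 14, 59402009 to 59440884, 8.35 ± 1.93 to 54.8 ± 19.3 CPM, 2.72 ± 0.24), Fam107a (2.65 ± 0.38), the p53 target Trp53inp1 (2.63 ± 0.30), Serpina3n, Cyp2b10 (2.39 ± 0.44) and the glycogen-targeting phosphatase subunit Ppp1r3g (2.30 ± 0.56). Cyp2b10 has near-identical relatives. Of 13 mitochondrially encoded mRNAs 5 were lower and 0 higher (5 adjusted over the list alone, 11 with library totals, median -0.81, camera adjusted p = 0.101). Of all 14280 genes 7198 had no overlap between the libraries of the groups, where chance gives 5.71% for 3 against 4.

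Against saline, the pretreated livers still had more of many inflammatory mRNAs. Il1b was 28.5 ± 6.51 CPM against 0.915 ± 0.379 CPM in saline (log2 fold change 4.94 ± 0.28), Cxcl10 was higher by 4.92 ± 0.24, Tnf by 4.91 ± 0.45 and Acod1 by 8.86 ± 0.43. The plasma protein mRNA Plg lay above the saline level (1386 ± 334 to 3918 ± 214 CPM, adjusted p = 7.73e-06), and that of the transcription factor Foxa3 far below it (-4.79 ± 0.31, adjusted p = 6.07e-09). In this comparison 4969 genes were higher and 4313 lower, of which 2544 and 2780 by at least 2-fold. With library totals the counts were 1683 and 6803, so the higher share fell from 53.5% to 19.8% and the median of all genes went from 0.14 to -0.54. More genes were lower than higher also in the fit of only the groups compared (3843 higher, 4602 lower), with no filter on low counts (4260, 4883) and on unfiltered FPKM (4000, 4404).

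Of 21 cytokine and chemokine genes 17 were higher and 0 lower (17 adjusted over the list alone, median 4.92, or 4.90 with 3 genes at their bound; adjusted p = 0.0753 with an estimated correlation). Ccl5 was higher by 5.47 ± 0.21 and Cxcl2, with saline counts in saline 3 alone, by 7.48 ± 1.03. All 9 monocyte markers (9 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation) and 11 of 12 neutrophil markers (11; adjusted p = 0.0764 with an estimated correlation) were higher, with Cd14 at 4.65 ± 0.25, Il1r2 at 7.23 ± 0.40 and Mmp8 at 6.34 ± 0.31. Interferon response genes were higher in 15 and lower in 3 of 23 cases (15 and 3 adjusted over the list alone; adjusted p = 0.449 with an estimated correlation), with Gbp2 at 5.07 ± 0.31. Necroptosis and pyroptosis genes were higher in 9 and lower in 1 of 13 cases (10 and 2 adjusted over the list alone, 5 and 2 with library totals; adjusted p = 0.354 with an estimated correlation), with Casp4 at 3.38 ± 0.20. Kupffer cell markers were higher in 9 of 12 cases (9 adjusted over the list alone, Cd68 2.05 ± 0.23) and endothelial markers in 11 of 12 (11, Dnase1l3 1.62 ± 0.19, Stab1 1.41 ± 0.18). With library totals 5 Kupffer cell and 7 endothelial markers were higher. Both lists had adjusted p = 0.561 with an estimated correlation. Large rises were also those of Slfn4 (7.31 ± 0.36), of a gene family with similar sequences, and the inflammasome gene Mefv. Mefv had 2 counts in saline and 372 in pretreated livers, a ratio of 228 with a 95% counting interval from 62.8 to 1890.

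Of 18 hepatocyte transcription factors 14 were lower and 2 higher (14 and 2 adjusted over the list alone, median -2.42), with Prox1 at -3.40 ± 0.21 and Nr1h4 at -1.96 ± 0.12. The median was -3.10 with library totals, and the camera call gave adjusted p = 0.0573 with an estimated correlation. Large falls were those of Tbx3 (chromosome 5, 119670669 to 119684724, -5.79 ± 0.54), Hhex (-4.94 ± 0.26), Tsku (-4.86 ± 0.37), Inhbe (-5.76 ± 0.33), Hdhd3 (-5.63 ± 0.28), Usp2 (-5.10 ± 0.22) and Nags (-4.81 ± 0.20). In contrast, 17 of 18 plasma proteins were higher (17 adjusted over the list alone, median 0.94), with Apob at 1.34 ± 0.20, Serpinc1 at 1.10 ± 0.16 and Alb at 0.98 ± 0.25. With library totals 7 were higher and 1 lower (median 0.26), Alb was no longer called (0.28, adjusted p = 0.162; 0.116 on unfiltered FPKM), and the list had adjusted p = 0.561 with an estimated correlation.

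Acute-phase genes were higher in 15 of 21 cases (15 adjusted over the list alone, 7 higher and 1 lower with library totals), with Cp at 1.58 ± 0.19 and complement C3 at 1.66 ± 0.24. P450 genes were higher in 13 of 16 cases (13 adjusted over the list alone, 7 higher and 1 lower with library totals), with Cyp2b10 at 3.81 ± 0.48 and Cyp2c29 at 2.04 ± 0.24, both with close relatives. Bile acid genes were higher in 13 and lower in 2 of 18 cases (13 and 2 adjusted over the list alone, 8 and 3 with library totals), with the export pump Abcb11 at 1.79 ± 0.19 and Cyp27a1 at 1.80 ± 0.20. With an estimated correlation these 3 lists had adjusted p = 0.729 (acute-phase), adjusted p = 0.553 (P450) and adjusted p = 0.561 (bile acid). Cholesterol synthesis genes were divided, with 8 higher and 7 lower of 20 (8 and 7 adjusted over the list alone), with Nsdhl at 1.54 ± 0.20 among the higher. Their median of 0.28 flipped to -0.40 with library totals (4 higher, 9 lower). All 27 ribosomal protein mRNAs were higher (27 adjusted over the list alone, median 0.91, Rpl4 1.26 ± 0.13; adjusted p = 0.463 with an estimated correlation), but 8 with library totals (median 0.24). With library totals the medians of apoptosis, p53, fatty acid, gluconeogenesis, urea cycle, cAMP, heat shock, unfolded protein response, ferroptosis, cell cycle and stellate cell lists also changed sign. Camera called 18 of 38 lists, and 0 with an estimated correlation. In 8825 of 14280 genes the libraries of the groups did not overlap, where chance gives 5.71%.

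**Figure D3:**
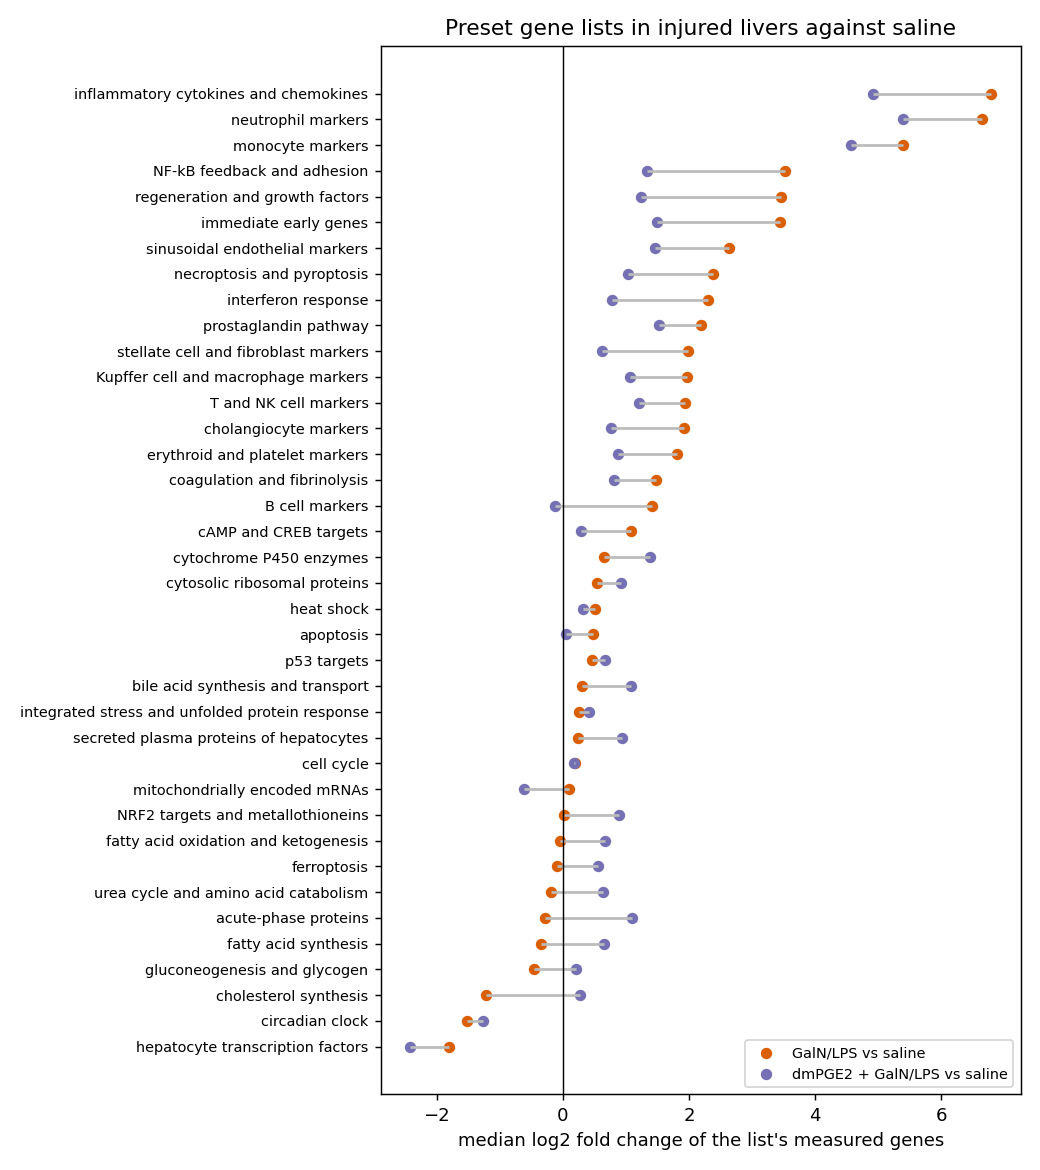
Median log2 fold change of the 38 tested gene lists in GalN/LPS against saline (orange) and pretreated against saline (purple) livers, 1 point per list and comparison, TMM-scaled. The plasma protein list moved from 0.23 to 0.94 (0.26 with library totals) while the hepatocyte transcription factor list stayed below 0, at -1.81 and -2.42, and several metabolic lists of the pretreated livers, such as cholesterol synthesis (0.28), changed sign with library totals (-0.40).

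Pretreatment moved 3048 of the 7556 genes that GalN/LPS had changed in the opposite direction, or 40.3%, where independent changes would give 2066. With TMM the number above independence lay among the genes that GalN/LPS had raised, such as Il1b and Irf1. Of those 3906, 2218 fell with pretreatment, against 1176 under independence, and 577 rose further. Of the 3650 lowered genes 830 rose, against 890 under independence, and 909 fell further. Under library totals the numbers were 2478 fallen of 3067 raised genes, against 1461 under independence, and 223 risen of 4277 lowered genes, against 184. In 20 simulated sets without any group difference the 2 comparisons had a mean correlation of -0.531 through the shared group, and in the data -0.494, with covariances of -0.0506 and -0.686. Calls are rare without group differences, so the simulated mean of 0.05 opposite calls says little about the 3048. Both comparisons share the 3 GalN/LPS libraries, which are too few to be split between them, so the overlap is not free of their shared error. Among the 3048 genes, 1509 remained on the same side of saline, 1387 were not called against saline and 152 had passed to its other side. The raised genes had a median log2 fold change of 1.66 in GalN/LPS and 1.05 in pretreated livers against saline, and the lowered genes -1.01 and -1.15. These medians and the sides of saline are with TMM and were not computed with library totals. With totals the median of all genes went from 0.03 to -0.15 in GalN/LPS and from 0.14 to -0.54 in pretreated against saline livers. How far the genes returned toward saline thus depends on the scaling. The genes were also picked by their GalN/LPS change.

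The interaction test, of whether the effect of dmPGE2 differed between injured and uninjured livers, called 4999 genes. Chance was not excluded for this count. With the injured groups kept intact, 2 splits that mixed saline and dmPGE2 labels still called 3703 and 3825 genes. The time after dmPGE2 may also differ between the groups. The interaction term was positive for 2202 genes and negative for 2797, of which 559 and 2088 by at least 2-fold. Among the genes with a negative term was Nfkbia (-2.07 ± 0.19, adjusted p = 5.76e-05), whose mean was 23.8 ± 3.18 CPM in saline, 20.6 ± 2.81 CPM in dmPGE2, 154 ± 12.1 CPM in GalN/LPS and 31.7 ± 2.63 CPM in pretreated livers. The gluconeogenic enzyme Pck1 had a positive term (2.30 ± 0.25, adjusted p = 8.68e-05), from -1.08 ± 0.18 in uninjured (adjusted p = 0.0628) and 1.22 ± 0.17 in injured livers. With library totals 182 terms were positive and 5209 negative, so the positive share fell from 44.0% to 3.4%, and the median of all genes from -0.11 to -0.69. Without GalN/LPS 3 there were 1370 positive terms.

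NF-kB feedback genes had a negative term in 14 of 17 cases and a positive one in 0 (14 adjusted over the list alone; adjusted p = 0.117 with an estimated correlation). For cytokines the term was negative in 9 of 21 cases (9 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), with Il1b at -3.25 ± 0.39 and Cxcl10 at -2.43 ± 0.33. Tnf was not past the test (-1.30 ± 0.90, adjusted p = 0.272), but was with limma-trend on FPKM, and moved to -0.65 without dmPGE2 1. Irf1 was negative at -1.96 ± 0.20, one of 11 negative among 23 interferon response genes (11 adjusted over the list alone, 21 with library totals; adjusted p = 0.435 with an estimated correlation). Immediate early genes were negative in 9 of 20 cases (9 adjusted over the list alone; adjusted p = 0.441 with an estimated correlation), with Fosl2 at -2.35 ± 0.33 and Klf6 at -2.15 ± 0.33. Of 22 apoptosis genes 12 were negative and 2 positive (13 and 2 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), with Mcl1 at -1.46 ± 0.20 and Cflar at -1.34 ± 0.20. Of 13 necroptosis and pyroptosis genes 6 were negative and 0 positive (6 and 1 adjusted over the list alone), with Casp4 at -1.73 ± 0.29. Endothelial markers were negative in 11 of 12 cases (12 adjusted over the list alone), with Dnase1l3 at -2.51 ± 0.27 and Clec4g at -2.10 ± 0.22, and Kupffer cell markers in 11 of 12 (12), with Adgre1 at -2.39 ± 0.37 and Csf1r at -1.42 ± 0.27. Both had adjusted p = 0.435 with an estimated correlation. Dcn of the stellate cell list (5 of 11 negative, 6 adjusted over the list alone, 9 with library totals; adjusted p = 0.459 with an estimated correlation) was at -1.83 ± 0.46.

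Positive terms included genes of hepatocyte metabolism, fewer of them with library totals. Cholesterol synthesis genes were positive in 12 of 20 cases (13 adjusted over the list alone, 9 with library totals), with Msmo1 at 1.86 ± 0.28 and Fdft1 at 1.68 ± 0.26. Plasma protein genes were positive in 15 of 18 cases (18 adjusted over the list alone, 4 with library totals), with Serpinc1 at 1.07 ± 0.23 and Apoa1 at 1.19 ± 0.25. Alb was positive at 1.15 ± 0.36 (adjusted p = 0.0243), but near the threshold. It did not pass without GalN/LPS 1 (1.03, adjusted p = 0.0612), GalN/LPS 3 (1.10, 0.0512), pretreated 3 (1.01, 0.0601), pretreated 4 (1.02, 0.0557) or dmPGE2 1 (1.12, 0.0561), nor with library totals (0.57, 0.0802), the replicate number as a block (0.99, adjusted p = 0.102) or unfiltered FPKM (1.06, 0.24). Fatty acid synthesis genes were positive in 7 of 15 cases (9 adjusted over the list alone, 4 with library totals), with Fads1 at 1.78 ± 0.31. All 3 lists had adjusted p = 0.435 with an estimated correlation. Urea cycle and amino acid genes were positive in 6 of 16 cases (8 adjusted over the list alone, 1 with library totals; adjusted p = 0.441 with an estimated correlation), with Tat at 2.58 ± 0.45. Ribosomal protein mRNAs were positive in 18 of 27 cases (21 adjusted over the list alone; adjusted p = 0.441 with an estimated correlation), with Rpl11 at 0.73 ± 0.18, but in 0 with library totals, where the median flipped from 0.57 to -0.01. Large positive terms belonged to Ppp1r3g (chromosome 13, 35958839 to 35970388, 4.78 ± 0.85), Igfbp1 (3.18 ± 0.83), Trp53inp1 (3.06 ± 0.42), Hamp (3.04 ± 0.77) and the retinoic acid hydroxylase Cyp26a1 (3.00 ± 0.60). Igfbp1 moved to 1.92 without saline 3 and was not past the test on FPKM (adjusted p from 0.0506 to 0.125). Large negative terms included Akap12 (-4.19 ± 1.08) and Onecut1 (-4.09 ± 1.13), the latter -2.31 and not past the test without GalN/LPS 2 (adjusted p = 0.0905), with voom (-2.62, adjusted p = 0.209) or on unfiltered FPKM (adjusted p = 0.0569). Camera called 20 of 38 lists for this term, and 0 with an estimated correlation.

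dmPGE2 alone left no gene past the adjusted threshold against saline in edgeR. Unadjusted p lay under 0.05 for 1990 of 14280 genes, where 714 would be expected by chance, and the smallest adjusted p was 0.0628. In 3761 genes the libraries of the groups did not overlap, where chance gives 10%. DESeq2 called 137 genes higher and 150 lower, and voom with quality weights 504 and 340. EdgeR without a filter on low counts called 290 and 171. Limma-trend on log2(FPKM + 1) called 1 higher and 0 lower. Without saline 1 edgeR called 1 higher and 3 lower, and without saline 3 it called 1 and 1. Cyp2b10, a target of the xenobiotic receptor CAR, was 3.95 CPM in saline and 24.0 CPM in dmPGE2 livers (2.60 ± 0.47, adjusted p = 0.0628). Serpina3n was at 1.92 ± 0.41 (adjusted p = 0.0795), Ppara at 1.09 ± 0.21 (adjusted p = 0.0716) and Pck1 at -1.08 ± 0.18 (adjusted p = 0.0628, and 0.028 without saline 1). The mitochondrial mRNA mt-Co3, which overlaps the more abundant mt-Atp6, was at -2.85 ± 0.46 (adjusted p = 0.0628, and 0.000166 without saline 3). It had only 17418 counts over all 13 libraries, while mitochondrial genes together took at least 2.58% of every library. Its change is therefore uncertain, and the reason for its few counts was not tested. DESeq2 gave these 5 genes adjusted p from 1.47e-08 for Pck1 to 0.00374 for Serpina3n. Over all settings their adjusted p ranged from 5.14e-52, for mt-Co3 in edgeR without a filter on low counts, to 0.255, for Serpina3n without dmPGE2 2. In the unfiltered fit the change of mt-Co3 was about the same size (-2.82) as in the main one. That fit was not tried on simulated data, so its small p-values and its 290 and 171 calls are uncertain.

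Inflammatory genes in uninjured livers did not pass either, with Il1b at 0.72 ± 0.33 (adjusted p = 0.346) and Tnf at -0.56 ± 0.78. Tnf ranged from -1.19 without dmPGE2 1 to -0.14 without dmPGE2 2, and Il1b was 0.44 without saline 2. Alb was at -0.43 ± 0.26 (adjusted p = 0.483). Adjusted over the list alone, mitochondrially encoded mRNAs were lower in 5 of 13 cases (median -0.78), interferon response genes in 4 of 23 (median -0.30), plasma proteins in 2 of 18 (median -0.27) and cAMP targets in 2 of 18 (median -0.19). Camera called these 4 lists down, with adjusted p = 2.18e-07, adjusted p = 2.37e-05, adjusted p = 0.00217 and adjusted p = 0.0143. It also called ribosomal proteins (0.000242), immediate early genes (0.0143) and B cell markers (0.014) down, and Kupffer cell markers up (0.00217). Of the lists it did not call, 3 of 15 fatty acid synthesis and 2 of 18 stress and unfolded protein response genes were lower. Acute-phase genes were higher in 2 and lower in 1 of 21 cases, hepatocyte transcription factors in 2 and 2 of 18, and gluconeogenesis and glycogen genes in 2 and 2 of 14, all adjusted over the list alone. With an estimated correlation none of the 8 held, at adjusted p = 0.678 for the mitochondrial, interferon, cAMP and B cell lists and adjusted p = 0.951 for the others. In 9 of 10 splits of the same libraries, the real one included, camera with the preset correlation called at least 8 lists. Fry, which asks whether the genes of a set move one way and not whether they differ from other genes, called 0 lists, with 0.179 as its smallest adjusted p. Its test for change in either direction called 10, with adjusted p = 0.000244 for gluconeogenesis and glycogen, 0.00712 for cAMP targets and 0.00849 for hepatocyte transcription factors.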

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

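The tests of a lower share of hepatocyte RNA and of the scaling between libraries were chosen after the values that decide them were seen, as was the look at the share of opposite calls in other splits. The tests of gene length and expression, of a few abundant genes and of a label swap were chosen after their pattern was seen but before their own result, and the tests of other splits were planned.

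The interaction test, of whether the effect of dmPGE2 differed between injured and uninjured livers, called 2202 genes with a positive and 2797 with a negative term. Named genes with negative terms were Akap12 (-4.19), Onecut1 (-4.09), Il1b (-3.25), Dnase1l3 (-2.51), Cxcl10 (-2.43), Adgre1 (-2.39), Fosl2 (-2.35), Klf6 (-2.15), Clec4g (-2.10), Nfkbia (-2.07), Irf1 (-1.96), Dcn (-1.83), Casp4 (-1.73), Mcl1 (-1.46), Csf1r (-1.42) and Cflar (-1.34). Those with positive terms were Ppp1r3g (4.78), Igfbp1 (3.18), Trp53inp1 (3.06), Hamp (3.04), Cyp26a1 (3.00), Tat (2.58), Pck1 (2.30), Msmo1 (1.86), Fads1 (1.78), Fdft1 (1.68), Apoa1 (1.19), Alb (1.15), Serpinc1 (1.07) and Rpl11 (0.73). Several calls changed with single libraries, the scaling or the model. The positive count was 1370 without GalN/LPS 3, and with library totals 182 terms were positive and 5209 negative. Alb stayed near 1 but was not past the test without GalN/LPS 1 (1.03, adjusted p = 0.0612), GalN/LPS 3 (1.10, adjusted p = 0.0512), pretreated 3 (1.01, adjusted p = 0.0601), pretreated 4 (1.02, adjusted p = 0.0557) or dmPGE2 1 (1.12, adjusted p = 0.0561), with the replicate number as a block (0.99, adjusted p = 0.102) or on unfiltered FPKM (1.06, adjusted p = 0.24), and was at 0.57 with library totals (adjusted p = 0.0802). Onecut1 was not without GalN/LPS 2 (-2.31, adjusted p = 0.0905), with voom (adjusted p = 0.209) or on unfiltered FPKM (adjusted p = 0.0569). Igfbp1 was at 1.92 without saline 3, and Rpl11 at 0.16 with library totals (adjusted p = 0.488).

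In the pretreated group, the one group of 4 libraries, 6 of 116 measures had 1 library far from the other 3, where chance gives about 1 in 20, or 5.8. Pretreated 2 stood apart on the first principal component (43.2, the nearest other 35.9, Dixon ratio 0.868). Pretreated 4 stood apart in log2 CPM for Cd14 (0.874), Fam107a (0.866), Il1r2 (0.859) and Acacb (0.833), and pretreated 3 for Ptgs2 (0.868).

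Other divisions of the same libraries into groups of the same sizes were used to ask whether chance could give as many calls. For pretreated against GalN/LPS chance was argued against for the gene count (7780, highest other 5104), with 1 of 35 splits as large. That is the smallest share 35 splits can give, and they do not tell what made the groups differ. The same held for pretreated against saline (9282, highest other 5255). For the interaction the count was 4999, with 3825 as the highest other of 100 splits. There dmPGE2 labels were exchanged in injured and uninjured livers together, which asks about any dmPGE2 effect and not the interaction alone. The other splits that kept the injured groups intact gave 3703 and 3825 genes, so chance was not excluded for the interaction. For the genes moved opposite to GalN/LPS the values were 3048 and 2777, but this count follows the number of calls. Opposite genes made up 39.2% of the calls in the real grouping and 54.4% in that other split, and both comparisons share a group in every split, so chance was not excluded for the reversal. Nor was it excluded for the counts of lists past camera in pretreated against GalN/LPS (25, highest other 27, 5 of 35 splits as large), pretreated against saline (18, highest other 21, 9 of 35) and the interaction (20, highest other 28, 14 of 100). With 3 against 3 libraries the 10 splits are too few for a share under 0.05. For GalN/LPS against saline the real and highest other values were 7556 and 0 genes and 22 and 29 lists, and for dmPGE2 against saline 0 and 0 genes and 8 and 13 lists. As many lists as in the real grouping were called in 5 of 10 and 9 of 10 splits, so chance was not excluded for these lists. The other splits with the most genes for both comparisons of pretreated livers moved pretreated 2 to the other side. The 4 splits that moved 1 pretreated library called 965 to 5104 genes against GalN/LPS and 3315 to 5255 against saline, and they differ least from the real grouping.

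Against saline, pretreated livers had lower hepatocyte transcription factor mRNAs (median log2 fold change -2.42) and higher plasma protein mRNAs (0.94, standard error between libraries 0.108). A lower share of hepatocyte RNA would move both lists alike, and their difference of -3.36 argues against it as the whole cause, but not against a part in it. Scaling moves both lists alike and so is argued against for the gap between them, but it stays open how far plasma proteins lie above saline: with library totals their median was 0.26 (standard error between libraries 0.0590), with 7 of 18 higher and 1 lower, the transcription factors were at -3.10, and with TMM the plasma protein list had adjusted p = 0.561 with an estimated correlation. A trend with gene length and expression level cannot be told apart for the plasma proteins: without it the difference between the lists was -2.48 instead of -3.36, with 73.6% kept, but the plasma protein median became -0.20. The treatments stay open as biological explanations and were not tested.

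With library totals 8.3% of the calls in pretreated against GalN/LPS livers were higher, against 44.7% with TMM. If a few abundant genes took the counts of all others in pretreated livers, leaving them out of the totals should bring back the higher calls. Leaving out the 100 most abundant genes gave 13.9%, leaving out 10 gave 8.0% and leaving out 500 gave 28.6%, so a few genes are unlikely to be the whole cause. Which scaling is nearer the amounts per cell was not tested, since no RNA of known amount was used here.

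GalN/LPS 2 and pretreated 2 lay nearest each other among the injured livers of both groups. Their mean correlations across genes, which are not independent replicates, were 0.973 with their own group and 0.951 with the other for GalN/LPS 2, and 0.973 and 0.949 for pretreated 2. A swap of both labels is argued against, because exchanging them called 0 genes where the labels as given called 7780. A spread of injury within the groups stays open and was not tested.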

How the results depend on the processing

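The alternative that leaves out GalN/LPS 2 and pretreated 2 together was chosen after seeing the data, and the others were planned.

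Named genes were not examined in the alternative chosen after seeing the data, nor under the fold change threshold. Across the other alternatives no named gene changed sign past the test. Against the 5 comparisons in the order GalN/LPS against saline, pretreated against GalN/LPS, dmPGE2 against saline, pretreated against saline and interaction, 10, 10, 0, 3 and 15 values of named genes fell short of the threshold under an alternative, 3, 11, 17, 0 and 3 newly passed it, and 1080, 1247, 149, 877 and 695 stayed on their side.

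With library totals the counts of higher and lower genes were 616 and 6804 for pretreated against GalN/LPS, 1683 and 6803 for pretreated against saline, and 182 and 5209 for the interaction. Of the main calls 4915 of 7780, 5996 of 9282 and 2979 of 4999 were shared. The medians of all genes moved from -0.10 to -0.61, 0.14 to -0.54 and -0.11 to -0.69, and for GalN/LPS against saline from 0.03 to -0.15, where 41.8% of the calls were higher instead of 51.7%. Why the scalings differ so much was tested only for a few abundant genes, and otherwise the cause was not tested.

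A fold change of at least 2 left 1853 lower genes for GalN/LPS against saline, 518 higher and 2603 lower for pretreated against GalN/LPS, 2544 and 2780 for pretreated against saline, 559 positive interaction terms and 1781 genes moved opposite to GalN/LPS. Smaller counts follow from the stricter threshold, but the balance of calls moved too. The higher share went from 44.7% to 16.6% for pretreated against GalN/LPS and from 53.5% to 47.8% for pretreated against saline. It went from 44.0% to 21.1% for the interaction and from 51.7% to 59.1% for GalN/LPS against saline. The sizes of change thus differed between the directions.

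For dmPGE2 against saline, where edgeR called 0 genes with 1990 at an unadjusted p under 0.05, DESeq2 called 137 higher and 150 lower, voom with quality weights 504 and 340, edgeR without a filter 290 and 171, limma-trend on log2(FPKM + 1) 1 higher, and the same without a filter 7 and 3. The cause was not tested. The edgeR fit without a filter was not tried on simulated data, so its counts are uncertain. Leaving out 1 library gave 0 to 1 higher and 0 to 3 lower genes, with 1 and 3 without saline 1 and 1 and 1 without saline 3.

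With an estimated correlation camera called 10, 1, 0, 0 and 0 lists, in the same order of comparisons, instead of 22, 25, 8, 18 and 20. Fry called 29, 34, 0, 25 and 27, and for change in either direction 36, 37, 10, 37 and 34. Both camera runs used the same fit and lists and differed in the correlation setting alone. Fry asks another question, so its counts are not like those of camera. Which calls are nearer the truth was not tested.

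Leaving out 1 library moved the positive interaction terms from 2202 to between 1370 (without GalN/LPS 3) and 2705 (without GalN/LPS 2). The other gene counts above 10 stayed within 1.5 times: 3156 to 3805 higher and 3283 to 3826 lower for GalN/LPS against saline, 2477 to 3631 and 3469 to 4277 for pretreated against GalN/LPS, 4516 to 4864 and 3948 to 4233 for pretreated against saline, 2039 to 3011 negative interaction terms, and 2346 to 3242 genes moved opposite to GalN/LPS.

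The fit of only the groups compared gives no interaction. Without both libraries numbered 2, pretreated against GalN/LPS gave 3628 higher and 4303 lower genes, with 7069 of 7780 calls shared, and the interaction 2840 and 3247. With the replicate number as a block the counts were 2974 and 3715 for pretreated against GalN/LPS and 1558 and 2153 for the interaction. Libraries of the same number did not pair: 0 of 18 such pairs had a correlation above 0.1, and 3 of 13 libraries were nearest to one with their own number.

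Depth limits the genes near 0 counts in saline, such as Csf3 and Il6, to lower bounds. With 200 of 14280 genes changed, simulated changes of 1.5 fold were mostly missed (13.4% and 9% found). The adjusted threshold is less strict where more genes change, so these shares do not carry over to the comparisons of injured livers. In GalN/LPS against saline livers all 27 ribosomal protein mRNAs were called, at a median log2 fold change of 0.55.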

Other observations

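The tests in this part were not chosen after their results were seen, and no explanation is offered.

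Prostaglandin pathway mRNAs changed with the injury. Against saline 11 of 14 rose in GalN/LPS livers, 1 fell and 2 were not past the test (11 and 1 adjusted over the list alone; adjusted p = 0.0471 with an estimated correlation). The inducible cyclooxygenase Ptgs2 had 2 counts in saline and 441 in GalN/LPS livers, a ratio of 255 with a 95% counting interval from 70.2 to 2110, and the synthase Ptges rose by 3.74 ± 0.43. The receptor mRNAs Ptger4 (3.21 ± 0.57) and Ptger2 (1.66 ± 0.37) rose too. In pretreated against GalN/LPS livers 9 of 14 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0845), with Ptgs2 at -3.91 ± 0.55, Ptgir at -2.19 ± 0.45 and Ptger2 at -1.21 ± 0.35. Ptger4 was at -1.11 ± 0.46 (adjusted p = 0.0529), but passed under several alternatives, such as without pretreated 4 (-1.31, adjusted p = 0.0471), with DESeq2 (adjusted p = 0.0261) and with library totals (-1.63, adjusted p = 0.0108). Its reads are uncertain, as it overlaps the more abundant Ttc33. Against saline 10 of the 14 were higher in pretreated livers and 2 lower (10 and 2 adjusted over the list alone, 6 and 2 with library totals), with the transporter Slco2a1 at 1.53 ± 0.19 and Ptges3 at -1.79 ± 0.17, and Ptger2 was not past the test (0.45 ± 0.38, and 0.29 without pretreated 2). The degrading enzyme Hpgd was at 0.60 ± 0.24 in GalN/LPS livers (adjusted p = 0.0459), a call lost with library totals (adjusted p = 0.117), voom (adjusted p = 0.126), the replicate number as a block (adjusted p = 0.0727), only the groups compared (adjusted p = 0.0653) and FPKM (adjusted p from 0.0895 to 0.162), and without GalN/LPS 2 (0.19, adjusted p = 0.442), saline 1 (adjusted p = 0.101) or saline 3 (adjusted p = 0.153). In pretreated against GalN/LPS livers Hpgd was at 0.43 ± 0.23 (adjusted p = 0.114). It was at 0.85 without GalN/LPS 2 (adjusted p = 0.00181), 0.78 with voom (adjusted p = 0.00208), 0.28 without GalN/LPS 1 and 0.25 without GalN/LPS 3. With no filter on low counts it was at 0.40 (adjusted p = 0.0395), an uncertain call, since that fit was not tried on simulated data. Against saline Hpgd was at 1.04 ± 0.23 (0.34 with library totals, adjusted p = 0.131). With dmPGE2 alone Ptger4 was at -0.54 ± 0.70 and Hpgd at 0.44 ± 0.24, neither past the test. Ptger4 ranged from -1.10 without saline 2 to 0.52 without saline 1, so not even its direction held.

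Coagulation and fibrinolysis genes rose in 8 of 14 cases in GalN/LPS livers (8 adjusted over the list alone), with the protein C receptor Procr at 7.55 ± 0.35 and thrombomodulin Thbd at 5.13 ± 0.48. In pretreated against GalN/LPS livers 9 fell and 5 rose (9 and 5 adjusted over the list alone, 9 and 1 with library totals), with Procr at -1.86 ± 0.21 and Plaur at -1.98 ± 0.30 lower and F11 at 1.01 ± 0.14 higher. Against saline 11 were higher and 1 lower in pretreated livers (11 and 1 adjusted over the list alone, 5 and 1 with library totals; adjusted p = 0.094 with an estimated correlation), with Procr at 5.70 ± 0.35 and F11 at 1.09 ± 0.14. Circadian clock genes fell in 12 of 19 cases in GalN/LPS livers (12 adjusted over the list alone; adjusted p = 0.0579 with an estimated correlation), with Dbp at -3.25 ± 0.20 and Tef at -1.90 ± 0.14. They were lower in 14 of 19 cases in pretreated livers against saline (15 adjusted over the list alone; adjusted p = 0.0891 with an estimated correlation), with Dbp at -3.87 ± 0.19 and Per2 at -2.36 ± 0.22. Between both injured groups 3 rose, such as Cry2 (1.71 ± 0.20), and 7 fell, such as Per1 (-1.21 ± 0.19), with 1 and 11 under library totals. The p53 targets were mixed. In GalN/LPS livers 6 of 16 rose and 1 fell (8 and 2 adjusted over the list alone), with Cdkn1a at 5.35 ± 0.34. In pretreated against GalN/LPS livers 4 rose and 8 fell (4 and 8 adjusted over the list alone), with Trp53inp1 at 2.63 ± 0.30 and Mdm2 at -1.02 ± 0.17. Against saline Trp53inp1 was at 2.96 ± 0.31, Cdkn1a at 4.48 ± 0.33 and Mdm2 at -1.37 ± 0.17 in pretreated livers. Among regeneration genes, of which 11 of 18 rose and 2 fell in GalN/LPS livers (11 and 5 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), oncostatin M (Osm) had 2 counts in saline and 515 in GalN/LPS livers, a ratio of 298 with a 95% counting interval from 82 to 2460. In pretreated against GalN/LPS livers Gzmb was at -1.56 ± 0.31.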
